A study of Mus musculus with 12 samples.

How the data were processed

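Hippocampus with fimbria was taken from PS2APP and Non-Tg mice aged 7 or 15 months, with 3 libraries in each of the 4 groups and 12 in all. Per the labels, mice were perfused with buffered saline, the tissue was dissociated with papain, and live cells were sorted before droplet capture with the 10x Genomics 3' v2 chemistry and sequencing on a HiSeq4000. The submitters' processing notes name the aligner GSNAP and the mouse build GRCm38 (mm10). The tool that counted molecules and the clustering method are not given in the sources used here. The deposited count tables, as made by the authors, hold unique molecular identifier (UMI) counts per Ensembl gene and cell, with 1 library per table and no normalisation. A deposited cell table from the authors gives the exonic UMI counts per cell together with other, non-numeric entries, which are the library, the cluster and the cell type name of each cell. All 47374 cells of the count tables were found in that table, 0 columns lacked a library, and the lowest cell held 1000 exonic UMIs. The tables cover 52636 gene identifiers, of which 52403 have a symbol. Gene positions are GRCm38 coordinates from the GENCODE annotation.

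The authors' 20 cell type names were used as deposited and no cells were clustered again. UMIs were summed over the cells of each type in each library (pseudobulk), for libraries with at least 20 cells of the type, so that a mouse library and not a cell is the unit of replication. Genes were filtered per type with filterByExpr of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total 15) and scaled with TMM. A quasi-likelihood model with robust spread and 1 mean per group was fitted with edgeR, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. The comparisons were PS2APP minus Non-Tg as the mean of both ages, the same at 7 months and at 15 months, the difference between those (genotype by age), and 15 minus 7 months in Non-Tg. Microglia, astrocytes and oligodendrocytes had all comparisons, and the other types with enough cells had the first. Fold changes are on the log2 scale with their standard error (SE), and CPM are UMIs scaled to library size, given as means over the libraries of a group with their standard deviation (SD).

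Where a Non-Tg group held 0 UMIs of a gene, the fold is a lower bound against 3 counts over the group, and with 1 to 3 UMIs the ratio is given with its exact 95% counting interval. Intervals and bounds cover counting error only. On simulated data built from these counts, the both-age test in microglia recovered 18.4% of genes set to a fold of 1.5, 64% at a fold of 2 and 93.2% at a fold of 4. For astrocytes the shares were 18%, 80% and 100%, and for oligodendrocytes 14.3%, 70% and 92.4%. The simulation held no pairs of libraries and changed many genes at once, in astrocytes 50, 50 and 90 at these folds. The real astrocyte test called 6. With fewer changed genes the adjustment is stricter, so these shares can overstate recovery in astrocytes and oligodendrocytes. In the same both-age fits 10 genes set to no change were called in microglia, 10 in astrocytes and 6 in oligodendrocytes. At 7 months alone a fold of 2 was recovered for 30% of genes in microglia, 44% in astrocytes and 22% in oligodendrocytes.

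Gene lists were tested with camera of limma 3.58.1, with the correlation between genes preset at 0.01 and again with an estimated correlation, and with fry, adjusted over the lists within each type and comparison. There were 22 lists of pathways and states and 20 lists of cell type markers, taken from general knowledge of mouse brain cells, and whether other groups first drew any of them from this mouse line is not known here. The pathway and state lists cover disease-associated and homeostatic microglia, reactive and homeostatic astrocytes, disease-associated oligodendrocytes, myelin, oligodendrocyte precursor genes, lysosome, lipid handling, cholesterol synthesis, interferon response, major histocompatibility complex (MHC) classes I and II, cytokines and chemokines, complement, oxidative phosphorylation, mitochondrially encoded genes, cell cycle, heat shock, dissociation and immediate early genes, the integrated stress response, and transgene-related genes. Fry tests whether the genes of a list move on balance 1 way and does not compare them with other genes.

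Cell shares are percentages of annotated cells per library, for the 16 types with at least 100 cells. Genotype differences in shares were tested with an exact two-sided permutation of genotype within age, which has 400 arrangements and a smallest p of 0.005. Within 1 age the smallest p is 0.1. Shares of microglia with a UMI of each of 9 disease-associated genes were computed after thinning each cell to 1000 UMIs, with 0 cells left out, and the same shares in oligodendrocytes serve as the background of free RNA. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used for shares and plots.

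The comparisons, the gene lists, the alternatives and the rule for naming genes were chosen before the data were examined. For both ages together the rule takes the 12 largest rises and 8 largest falls per main cell type among genes past the threshold with at least 20 CPM in 1 group and all 3 PS2APP libraries on the same side of all 3 Non-Tg libraries at both ages, or the 5 genes with the smallest p where fewer than 5 qualify. For the single ages, genotype by age, and age in Non-Tg it takes the 5 largest each way at 20 CPM or more, for other cell types the 3 each way with the smallest adjusted p, and for each list described the 2 to 6 members with the smallest p. App, Psen2, Thy1, Prnp, Mapt and sex-linked genes are named throughout, and predicted genes, Xist, Tsix and Y-linked genes are not named as the largest changes. Other genes in the text were chosen after their values were seen, as said where they occur. Transcripts of close relatives (Ccl3 and Ccl4, H2-D1 and H2-K1, C4b and its paralog, the Serpina3 family, and the pseudogene Lamr1-ps1) share sequence, and the tables cannot show how such reads were assigned.

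The alternatives were DESeq2 size factors in the edgeR fit, the Wald test of DESeq2 1.42.0, limma voom, no low-count filter, leaving out the top 5% of cells by UMIs in each type and library, leaving out cells under 1000 UMIs, leaving out each library in turn, thinning to 500 UMIs or not at all, and a block. Labels give no batch, so the block uses the 6 pairs of libraries whose submitter identifiers are consecutive, each with 1 PS2APP and 1 Non-Tg library of the same age; that these were prepared together is not stated. Within such pairs the residual correlation of microglial expression was 0.153 to 0.422, against -0.396 to 0.04 for other pairs. In oligodendrocytes it was 0.206 to 0.668 against -0.571 to -0.025, and in astrocytes 0.097 to 0.36 against -0.305 to 0.074. Residuals were taken from group means, so high values for some pairs force low ones for others. The block cannot estimate age in Non-Tg. Each type was taken as a whole. Sub-cluster sizes were not tested between groups, and are given only per library for oligodendrocytes at 15 months, since the genes that define sub-clusters can change with genotype, so that a change within cells is not separated from a shift between states of a type.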

Results

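Gene expression was measured in 47374 single cells of the hippocampus and fimbria from 12 mouse libraries. PS2APP mice carry transgenes for mutant human presenilin 2, driven by the prion promoter, and mutant human amyloid precursor protein, driven by the Thy1 promoter, and they develop amyloid plaques; Non-Tg mice lack both. The 4 groups (Non-Tg and PS2APP at 7 and at 15 months) hold 3 libraries each. In replicate order, Non-Tg libraries at 7 months held 16290488, 14782433 and 13302779 UMIs, and PS2APP libraries 22992730, 12980590 and 12206875. At 15 months the totals were 27636501, 11162599 and 21330844 for Non-Tg and 12648639, 15640979 and 14638350 for PS2APP. Libraries held 2442 to 7278 cells with median depths of 3032 to 5627 UMIs per cell. Sample labels call every mouse female, while the design text calls the 15 month mice male and names a line that also carries a tau transgene. Y-linked genes summed to 133 to 243 CPM in the 6 libraries at 15 months and to 0.491 to 1.503 CPM in the 6 at 7 months, so age and sex differ together in these data. Mapt, the mouse tau gene, lay at 478 to 759 CPM in the 12 libraries.

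Transgene-related transcripts were higher in neurons and oligodendrocyte precursors (OPC) of PS2APP mice, a comparison that asks where the 2 promoters are active. In excitatory neurons Thy1 (ENSMUSG00000032011, chromosome 9, 44043384 to 44048579), a neuronal surface glycoprotein, rose by 3.18 ± 0.16 log2 (SE). It went from 500 ± 20.2 to 5038 ± 429 CPM at 7 months and from 550 ± 177 to 4448 ± 1058 CPM at 15 months (SD, 3 libraries per group, but 2 for PS2APP at 15 months, where replicate 2 held 9 such cells). Psen2 (ENSMUSG00000010609, chromosome 1, 180227004 to 180263438), a subunit of gamma-secretase, rose by 3.92 ± 0.31, and Prnp (ENSMUSG00000079037, chromosome 2, 131909928 to 131938429), the prion protein gene, by 1.62 ± 0.14. In OPC Psen2 rose by 2.40 ± 0.22 and Prnp by 1.52 ± 0.13 (adjusted p = 0.000139 for each), while Thy1 had a value of 0.83 ± 0.26 (adjusted p = 1, and 0.0209 with the block) and App of 0.10 ± 0.17 (adjusted p = 1). Reelin cells had Thy1 higher by 2.43 ± 0.13 (adjusted p = 2.74e-09), while their Psen2 value of 1.06 had an adjusted p of 0.0812 (0.0033 with the block, and higher in PS2APP in 6 of 6 pairs). App itself had a value of 0.38 ± 0.14 (adjusted p = 1) and Mapt of -0.07 in excitatory neurons. The edgeR adjusted p in excitatory neurons was 5.81e-09 for Thy1 and 1.02e-05 for Psen2 and for Prnp. Chosen after their values were seen, Tyrobp (adjusted p = 0.00663, and 0.766 with the block) and Cst7 (0.0114) also rose there. So did the pseudogene Lamr1-ps1 (chromosome 2, 131904086 to 131904959), at 0 CPM in Non-Tg neurons (adjusted p = 0.0114), and in OPC (0.000633). Whether free RNA from microglia accounts for Tyrobp and Cst7 in neurons was not tested. Reads from the human transgenes cannot be separated from mouse reads in these tables.

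Astrocytes made up a smaller mean share of the cells in PS2APP libraries, in the comparison that asks whether genotype shifts cell type composition. Their share was 9.98% ± 1.77 in Non-Tg and 5.24% ± 1.43 in PS2APP at 7 months, and 8.81% ± 1.31 and 4.60% ± 2.08 at 15 months (SD, 3 libraries per group). It was lower in PS2APP in 6 of the 6 pairs of libraries with consecutive identifiers. T cells stood at 0.181% ± 0.12 and 0.533% ± 0.145 at 7 months and at 0.835% ± 0.614 and 1.79% ± 0.578 at 15 months, higher in PS2APP in 5 of the 6 pairs. Microglia differed by 4.26 percentage points (exact permutation p = 0.205), with 0.734 at 7 months and 7.79 at 15 months. Oligodendrocytes differed by 2.09 points (exact permutation p = 0.48), a mean of opposite signs with 8.515 at 7 months and -4.33 at 15 months. For astrocytes the mean difference of -4.48 points had an exact two-sided permutation p of 0.005, the smallest that 400 arrangements allow, and an adjusted p of 0.08 over 16 types. For T cells the difference of 0.655 points had an exact permutation p of 0.02 and an adjusted p of 0.16. No cell type passed the adjusted threshold. A single type at the smallest permutation p of 0.005 reaches an adjusted p of 0.08 over the 16 types. No type could therefore pass alone by this test, whatever its difference. Within 1 age the smallest possible p is 0.1. Dissociation and the live-cell sort set shares as well as the tissue does.

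**Figure D1:**
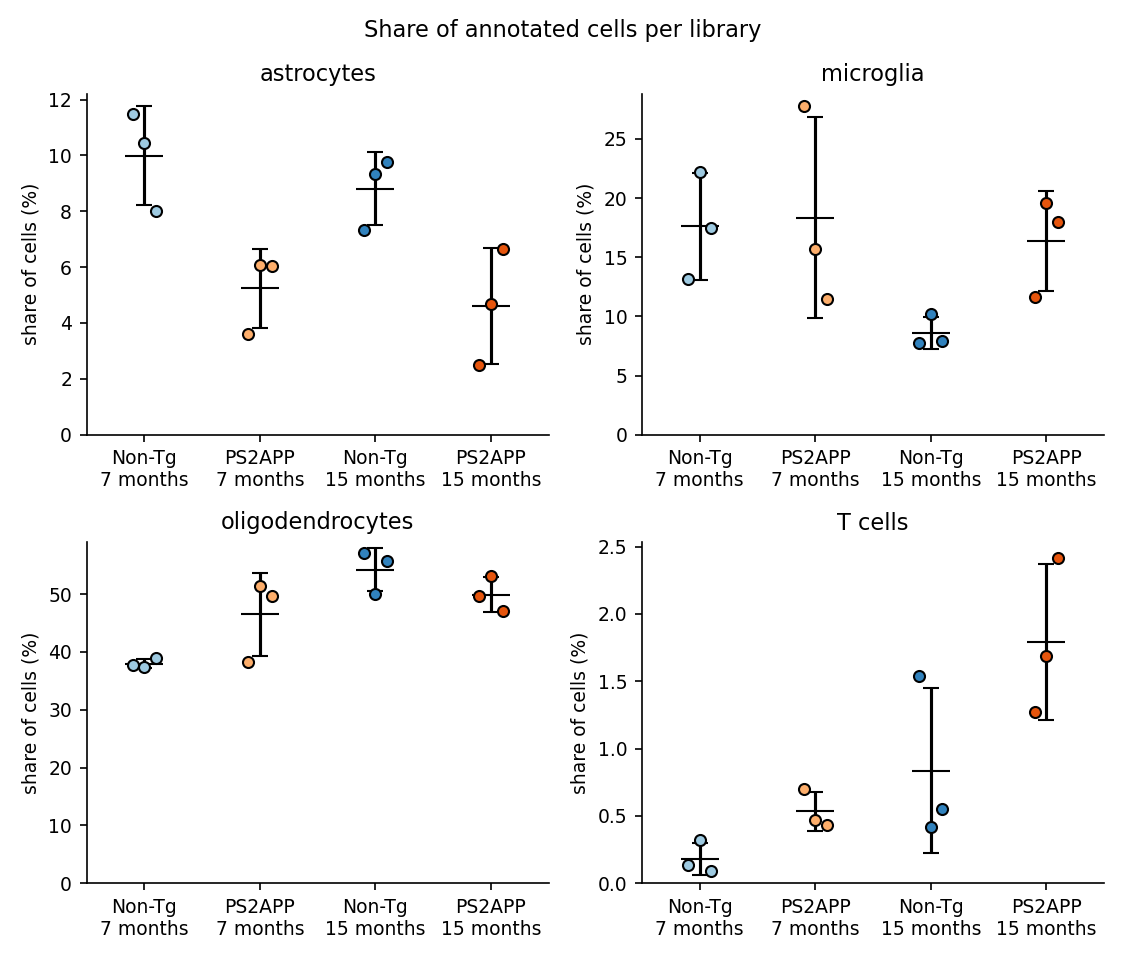
Share of annotated cells (%, linear axis) for astrocytes, microglia, oligodendrocytes and T cells in the 4 groups; points are libraries, bars the mean and SD of 3 libraries. Astrocyte means are 9.98% and 8.81% in Non-Tg and 5.24% and 4.60% in PS2APP at 7 and 15 months.

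A set of genes at low levels or undetected in Non-Tg microglia was higher in microglia of PS2APP mice, taken as a whole. Cst7 (ENSMUSG00000068129, chromosome 2, 150570415 to 150578944), which encodes the cysteine protease inhibitor cystatin F, rose by 6.93 ± 0.21 log2. It went from 17.0 ± 6.84 to 1839 ± 407 CPM at 7 months and from 14.8 ± 2.29 to 2056 ± 238 CPM at 15 months (SD, 3 libraries per group). Mamdc2 (ENSMUSG00000033207, chromosome 19, 23302609 to 23448442) had 0 UMIs in Non-Tg microglia and was at least 91.7-fold higher in PS2APP against a floor of 3 counts over the group. Igf1, insulin-like growth factor, rose by 5.82 ± 0.37, the secreted phosphoprotein gene Spp1 by 5.67 ± 0.46, and lipoprotein lipase (Lpl) by 5.26 ± 0.41. Tgm2, a transglutaminase, fell by 1.11 ± 0.17, from 146 ± 26.1 to 56.2 ± 19.8 CPM at 7 months and from 125 ± 13.5 to 68.6 ± 12.0 CPM at 15 months. Also among the 8 largest falls were the adhesion molecule Pecam1 with -1.12 ± 0.18, and the inhibitory lectin Siglece with -1.04 ± 0.17. The other large rises were Baiap2l2 (7.29 ± 0.28), Dkk2 (7.29 ± 0.61, on 4 Non-Tg UMIs), Tcap (6.45), Gpnmb (5.96), Hpse (5.18), Ch25h (5.14) and Cox6a2 (4.64), and the other falls were Tmem44 (-1.29), Bank1 (-1.27), Dok3 (-1.08), Slco4a1 (-1.07) and Tmem204 (-1.03). Adjusted p over these genes ran from 1.48e-10 for Cst7 to 0.00489 for Slco4a1.

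Across both ages 655 genes rose and 277 fell in microglia of 12356 tested (edgeR, adjusted p under 0.05). With the 6 pairs of libraries with consecutive identifiers as a block, 937 rose and 672 fell. Without Non-Tg 7 months replicate 2 the total was 605.

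**Figure D2:**
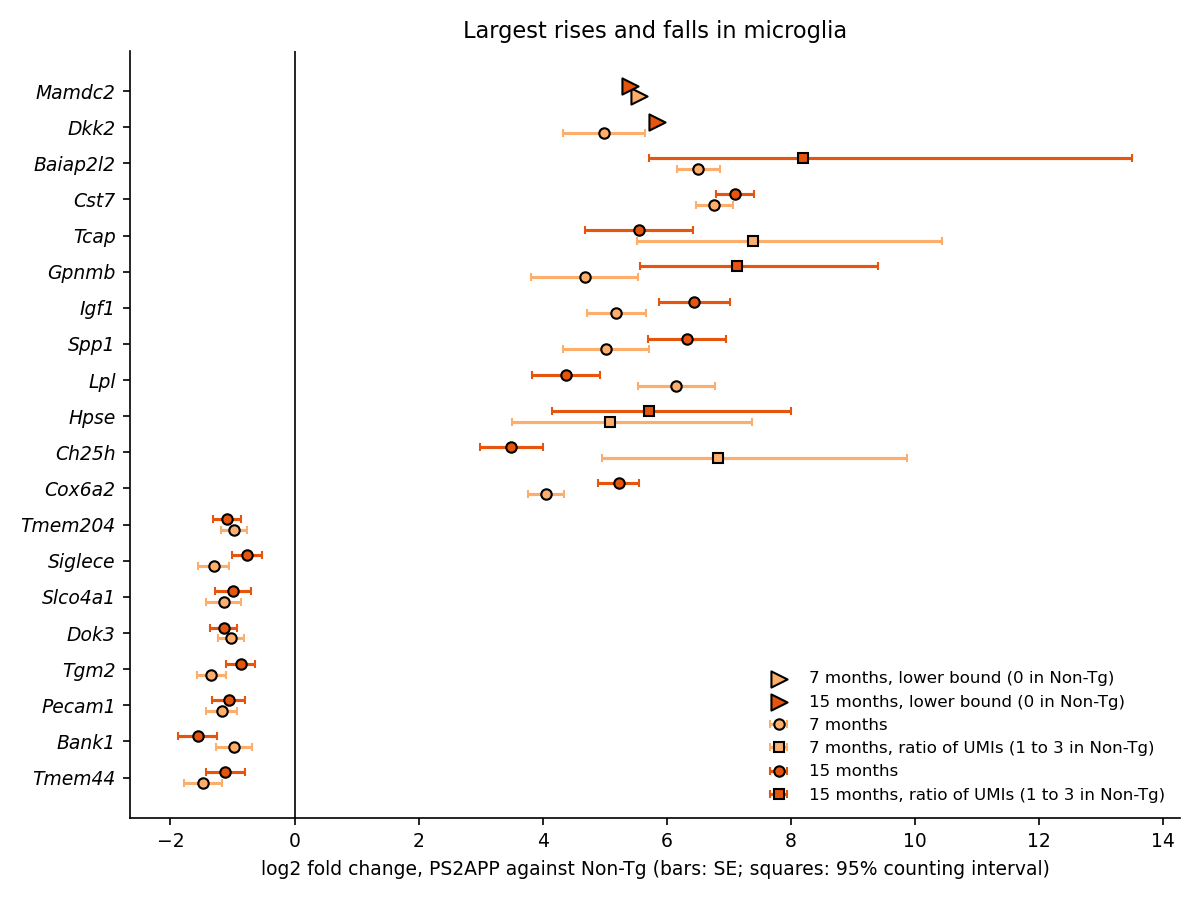
Log2 fold change of PS2APP against Non-Tg microglia at 7 and 15 months for the 12 largest rises and 8 largest falls over both ages; circles are edgeR estimates with SE, squares ratios of summed UMIs with 95% counting intervals where Non-Tg held 1 to 3 UMIs, and triangles lower bounds where it held 0. Mamdc2 was at least 47.2-fold higher at 7 months and at least 42.7-fold at 15 months.

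The genes grouped by function moved as follows in microglia. All 33 measured members of the disease-associated microglia list rose, among them Ank by 2.92 ± 0.11, a membrane protein that exports pyrophosphate, the integrin Itgax by 4.10 ± 0.24, and the glucan receptor Clec7a by 3.78 ± 0.22. Of 20 lysosome genes 15 rose (18 adjusted over the list alone), such as the tetraspanin Cd63 by 1.60 ± 0.13 and the protease cathepsin B (Ctsb) by 1.33 ± 0.12. Of 16 lipid handling genes 10 rose and 1 fell, with the same counts adjusted over the list alone. Apoe (ENSMUSG00000002985, chromosome 7, 19696109 to 19699188), an apolipoprotein, rose by 2.72 ± 0.22. It went from 2126 ± 723 to 11370 ± 4101 CPM at 7 months and from 2089 ± 468 to 17000 ± 2881 CPM at 15 months. Nceh1, a cholesteryl ester hydrolase, rose by 2.23 ± 0.14 and Plin2, a lipid droplet coat protein, by 1.72 ± 0.18, while clusterin (Clu) fell by 0.64 ± 0.15. Oxidative phosphorylation genes rose in 13 of 25 (19 adjusted over the list alone), with Ndufa1 at 1.57 ± 0.11 and Cox8a at 0.65 ± 0.13. Interferon response genes rose in 10 of 22 (17 adjusted over the list alone), with the antiviral synthetase Oas1a at 3.33 ± 0.51 and the tetherin gene Bst2 at 0.87 ± 0.17. Of 16 homeostatic microglia genes 5 fell (7 adjusted over the list alone). Tmem119 (ENSMUSG00000054675), a microglial membrane protein, stood at -0.78 ± 0.15, Bin1, an endocytosis gene, at -0.46 ± 0.10 and the selectin ligand Selplg at -0.48 ± 0.11. The chemokine receptor gene Cx3cr1 had -0.27 ± 0.16 (adjusted p = 0.345). Astrocyte marker transcripts moved with these groups: 4 of 7 fell in microglia (6 adjusted over the list alone), Aldoc by 0.90 ± 0.14. The mean share of astrocytes among the cells was also lower in PS2APP libraries. Whether free RNA from astrocytes bears on these falls, and on that of Clu, was not tested.

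By camera with the preset correlation 13 of 22 pathway and state lists passed in microglia. Disease-associated microglia genes (adjusted p = 6.44e-59) and lipid handling genes (adjusted p = 1.36e-07) held with an estimated correlation, with adjusted p = 0.00872 and 0.0102. The calls were lost for lysosome (adjusted p = 3.46e-19, and adjusted p = 0.0633 with an estimated correlation), oxidative phosphorylation (2.56e-12 and adjusted p = 0.123 with an estimated correlation) and interferon response (3.12e-12 and adjusted p = 0.133 with an estimated correlation). They were also lost for homeostatic microglia (0.000134 and adjusted p = 0.163 with an estimated correlation) and the astrocyte markers (4.6e-05 and adjusted p = 0.0602 with an estimated correlation). The Selplg call was lost without Non-Tg 7 months replicate 2 or 3, PS2APP 7 months replicate 2 or Non-Tg 15 months replicate 1 (highest adjusted p = 0.0599, lowest over its alternatives 0.000825). Complement genes (0 of 8, adjusted p = 0.193), myelin genes (0 of 19, 0.115), OPC genes (0 of 12, 0.12), and mitochondrially encoded genes (0 of 12, 0.193) did not pass as lists. Neither did cell cycle genes (1 up of 10, 0.29), heat shock genes (1 up of 13, 0.361), dissociation genes (2 down of 22, 0.139), transgene-related genes (1 up of 5, 0.139) and integrated stress response genes (3 up and 1 down of 16, 0.937), with the same counts adjusted over the list alone.

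The share of microglia with a UMI of the disease-associated genes was higher in PS2APP mice for all 9 genes tested. With each cell thinned to 1000 UMIs, Cst7 was seen in 1.43% ± 0.724 of Non-Tg and 34.6% ± 5.87 of PS2APP microglia at 7 months, and in 1.33% ± 0.611 and 36.1% ± 3.09 at 15 months (SD, 3 libraries per group). Clec7a differed by 16.5 percentage points, Lpl by 16.5, the growth factor gene Csf1 by 10.6, Igf1 by 10.3, the receptor kinase gene Axl by 7.33, Spp1 by 4.12, Itgax by 3.87 and Gpnmb by 2.02. The exact permutation p was 0.005 for each of the 9 genes, the smallest the design allows. Unthinned, the Cst7 difference was 44.0 points, at median depths of 2911 to 4982 UMIs per microglial cell. In oligodendrocytes thinned to the same depth, Cst7 was seen in 0.051% of Non-Tg and 2.83% of PS2APP cells at 7 months and in 0.008% and 1.89% at 15 months; their median depths were 2973 to 5794 UMIs. Csf1 was seen in 5.18% of Non-Tg and 6.29% of PS2APP oligodendrocytes at 7 months, above the 3.09% of Non-Tg microglia. At 15 months it was seen in 6.64% of Non-Tg and 9.37% of PS2APP oligodendrocytes, and in 3.52% of Non-Tg microglia.

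**Figure D3:**
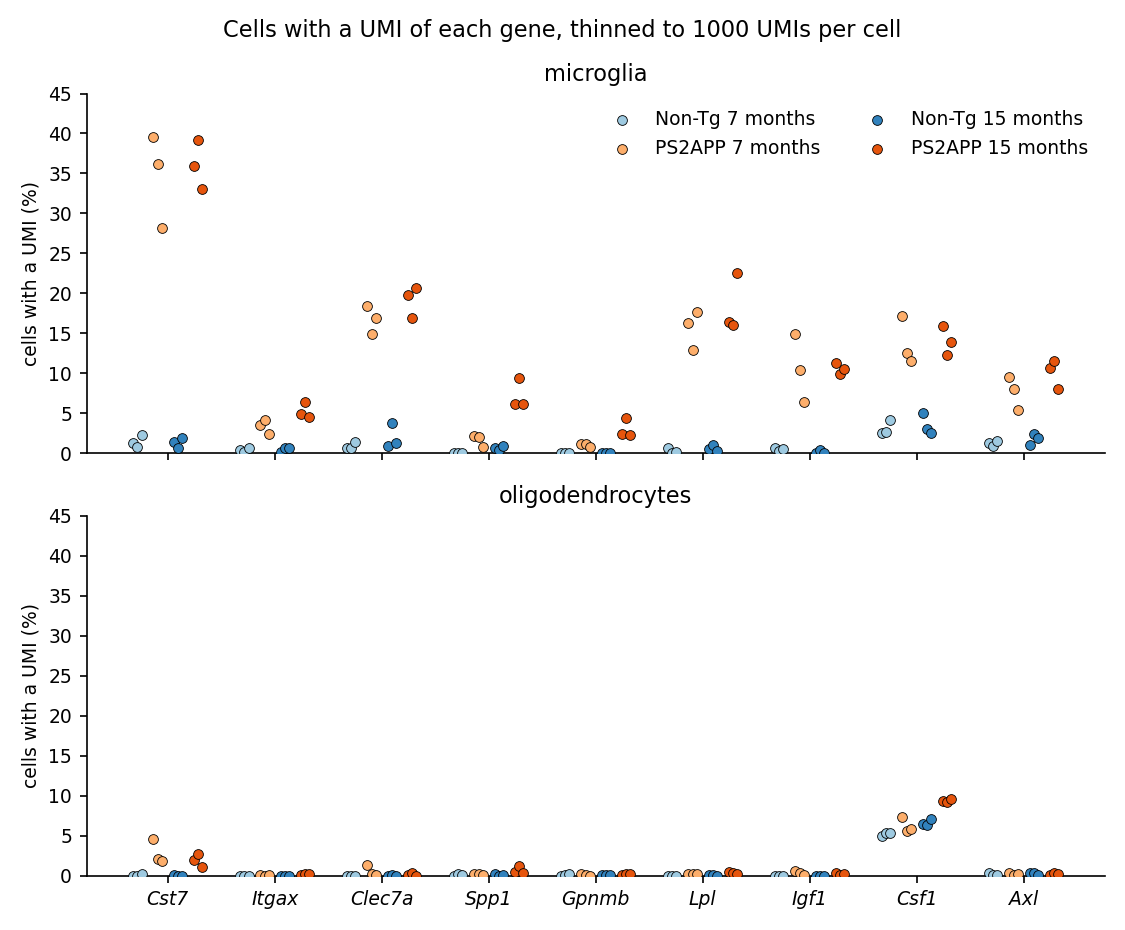
Percent of microglia and of oligodendrocytes with a UMI of each of 9 genes after thinning each cell to 1000 UMIs, with 1 point per library in the 4 groups. Cst7 reaches means of 34.6% and 36.1% in PS2APP microglia at 7 and 15 months, against 2.83% and 1.89% in PS2APP oligodendrocytes.

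At 7 months alone, the comparison for the younger mice, microglial Cst7 rose by 6.77 ± 0.29 and Baiap2l2 by 6.51 ± 0.34, and Mamdc2 was at least 47.2-fold higher. The ratio was 167 (95% interval 45.9 to 1380) for Tcap and 113 (31.1 to 938) for Ch25h, a cholesterol hydroxylase. The largest falls were Tmem44 (-1.47), Tgm2 (-1.34 ± 0.23), Siglece (-1.31), the ephrin receptor gene Epha2 (-1.29 ± 0.23) and Pecam1 (-1.18). By edgeR 219 genes rose and 33 fell (252, and 536 with the block). The disease-associated list rose in 29 of 33 genes (33 adjusted over the list alone; adjusted p = 9.11e-72, and 0.00298 with an estimated correlation). The total was 155 without Non-Tg 7 months replicate 1, 126 without PS2APP 7 months replicate 1, 117 without Non-Tg 7 months replicate 2 and 165 without PS2APP 7 months replicate 2. Siglece was not past the threshold without PS2APP 7 months replicate 1 or Non-Tg 7 months replicate 2 and Epha2 without the latter. Tmem44 and Pecam1 were each lost on 4 of the 12 omissions and Tcap by limma voom, and adjusted p over the alternatives of these genes reached 0.15.

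At 15 months, the comparison for the older mice, Cst7 rose by 7.09 ± 0.31 in microglia, Dkk2, a secreted Wnt antagonist, was at least 57.6-fold higher and Mamdc2 at least 42.7-fold. The ratio was 293 (52.3 to 11600) for Baiap2l2 on 1 Non-Tg UMI and 140 (47.7 to 680) for Gpnmb, a lysosomal glycoprotein gene. The largest falls were Fermt2 (-1.69 ± 0.39), Pex5l (-1.60 ± 0.34), the scaffold gene Bank1 (-1.56 ± 0.32), Trim59 (-1.38 ± 0.31) and Arrdc3 (-1.30 ± 0.30). Summed over each group, Pex5l, Fermt2 and Trim59 stood at 25.23, 14.44 and 11.80 CPM in Non-Tg at 7 months. They stood at 25.21, 12.56 and 11.15 CPM in PS2APP at that age, and at 65.86, 29.12 and 27.78 in Non-Tg at 15 months. Bank1 and Arrdc3 were lower in PS2APP at 7 months too. As a list, myelin genes were also more negative at 15 than at 7 months by camera, but not with an estimated correlation. Whether free RNA from oligodendrocytes bears on these 5 falls was not tested. In all, 321 genes rose and 60 fell (381, and 927 with the block). Of the disease-associated list 32 of 33 genes rose, each of the 33 when adjusted over the list alone (adjusted p = 1.09e-51, and 0.0135 with an estimated correlation). The total was 158 without Non-Tg 15 months replicate 1, 229 without PS2APP 15 months replicate 1, 1006 without Non-Tg 15 months replicate 2, 237 without PS2APP 15 months replicate 2 and 173 without Non-Tg 15 months replicate 3. Each of the 5 falls was lost on 2 to 6 of the 12 omissions, and Pex5l also with the block (adjusted p = 0.0551). The calls ended for Fermt2 and Trim59 without the top 5% of cells by UMIs and for Gpnmb by limma voom (0.0516), with adjusted p up to 0.163 over the alternatives of these genes.

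Astrocytes of PS2APP mice raised Gfap (ENSMUSG00000020932, chromosome 11, 102887336 to 102900912), the intermediate filament gene of reactive astrocytes, by 1.20 ± 0.17 log2 over both ages (adjusted p = 0.00118). It stood at 562 ± 144 against 971 ± 369 CPM at 7 months and 545 ± 53.8 against 1651 ± 121 CPM at 15 months. The other genes that rose are expressed mainly by microglia: the chemokine genes Ccl4 by 1.70 ± 0.22 and Ccl3 by 1.84 ± 0.28, the receptor gene Trem2 by 1.65 ± 0.25, and its adaptor Tyrobp by 1.91 ± 0.27. Cst7 had a ratio of 238 (95% interval 41.8 to 9510) on 1 Non-Tg UMI. Summed over the PS2APP libraries, Cst7 stood at 39.0 CPM in astrocytes, 26.8 in oligodendrocytes and 1926 in microglia. Whether free RNA from microglia accounts for these rises in astrocytes was not tested. At 15 months Aspg, an asparaginase gene, rose by 2.22 ± 0.40 and C4b, a complement component gene, by 1.77 ± 0.31 from 148 ± 50.6 to 513 ± 191 CPM. Of 16 reactive astrocyte genes 1 rose over both ages (7 adjusted over the list alone; adjusted p = 2.05e-15, and 0.0109 with an estimated correlation), with Serpina3n at 2.0 ± 0.48 (adjusted p = 0.565). Homeostatic astrocyte genes stood at 0 of 19 (0 adjusted over the list alone; adjusted p = 0.873).

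For the astrocyte comparison at both ages, 6 genes rose and 0 fell of 8562 tested with edgeR (242 at unadjusted p under 0.05; DESeq2 13, and 17 with the block). The 6 were kept whichever library was left out, and without PS2APP 15 months replicate 3 there were 10. At 7 months 2 rose, Ccl4 and Cst7 (3 with the block), and at 15 months 6 rose: Cst7, Gfap, Ccl4, Tyrobp, Aspg and C4b (12 with the block). Disease-associated microglia genes rose in 3 of 22 (9 adjusted over the list alone; adjusted p = 6.42e-20, and 0.00377 with an estimated correlation), beside 0 of 8 microglial markers (2 adjusted over the list alone; adjusted p = 0.669). The 7 month count was 0 without Non-Tg 7 months replicate 1 or 2 or PS2APP 7 months replicate 1, 1 without Non-Tg 7 months replicate 3 and 4 without PS2APP 7 months replicate 3. The 15 month count was 3 without Non-Tg 7 months replicate 2, PS2APP 7 months replicate 2 or PS2APP 15 months replicate 1, 2 without Non-Tg 15 months replicate 1 or PS2APP 15 months replicate 2, and 1 without Non-Tg 15 months replicate 3. C4b was lost on 10, Tyrobp and Ccl4 on 9 each and Aspg on 3 of the 12 omissions, with adjusted p up to 0.663 over their alternatives. At 15 months Tyrobp was also lost with the block, by limma voom and without the top 5% of cells by UMIs, C4b by limma voom and Ccl4 without the top 5% of cells.

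Oligodendrocytes of PS2APP mice raised Serpina3n (ENSMUSG00000021091, chromosome 12, 104406729 to 104414329), a secreted serine protease inhibitor gene, by 1.96 ± 0.18 log2 over both ages (adjusted p = 0.000411). It stood at 10.3 ± 1.9 against 21.8 ± 4.76 CPM at 7 months and 21 ± 5.85 against 149 ± 27.1 CPM at 15 months. C4b (ENSMUSG00000073418, chromosome 17, 34728380 to 34743882) rose by 1.53 ± 0.26, from 36.3 ± 20.4 to 61.7 ± 21.9 CPM at 7 months and from 93.7 ± 18.8 to 458 ± 95.1 CPM at 15 months (adjusted p = 0.0491). Gfap rose by 1.07 ± 0.11, at 17.8 ± 1.33 against 32.2 ± 2.13 CPM and 18.9 ± 2.55 against 46.1 ± 2.85 CPM at the 2 ages. Gfap rose in astrocytes too, and whether free RNA from astrocytes accounts for its rise here was not tested. Transcripts abundant in microglia rose as well, among them Cst7 by 6.63 ± 0.55, the chemokine gene Ccl6 by 2.86 ± 0.31, Lpl by 3.86 ± 0.52, Tyrobp by 1.92 ± 0.31, Ccl4 by 1.54 ± 0.24 and Ccl3 by 1.51 ± 0.26. In the PS2APP libraries, the 12 genes raised in both cell types lay at 78.0 to 111 times more UMIs per cell in microglia than in oligodendrocytes, and 9 constitutive microglial markers at 82.7 to 119 times more. Serpina3n was at 0.347 UMIs per oligodendrocyte and 0.0183 per microglial cell, and C4b at 1.05 and 0.0595.

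In oligodendrocytes 19 genes rose and 0 fell over both ages of 14665 tested with edgeR (333 at unadjusted p under 0.05; DESeq2 44, limma voom 8, and 25 with the block, 14 of them shared). Ccl6, Gfap, Serpina3n and Cst7 were kept whichever library was left out. Without PS2APP 15 months replicate 2 or Non-Tg 15 months replicate 1 the count was 4, without Non-Tg 7 months replicate 1 or 2 or Non-Tg 15 months replicate 3 it was 5, without PS2APP 15 months replicate 1 it was 6. Without Non-Tg 7 months replicate 3 it was 8, without PS2APP 7 months replicate 2 it was 9, without PS2APP 7 months replicate 1 it was 10 and without PS2APP 15 months replicate 3 it was 12. With the block, Tyrobp had an adjusted p of 0.149 and Ccl4 of 0.147, within 8.83e-30 to 0.164 and 1.44e-17 to 0.147 over all alternatives of each. Both were also lost by limma voom. Tyrobp was lost on 8, Ccl4 on 9, Ccl3 on 10, C4b on 11 and Lpl on 4 of the 12 omissions.

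**Figure D4:**
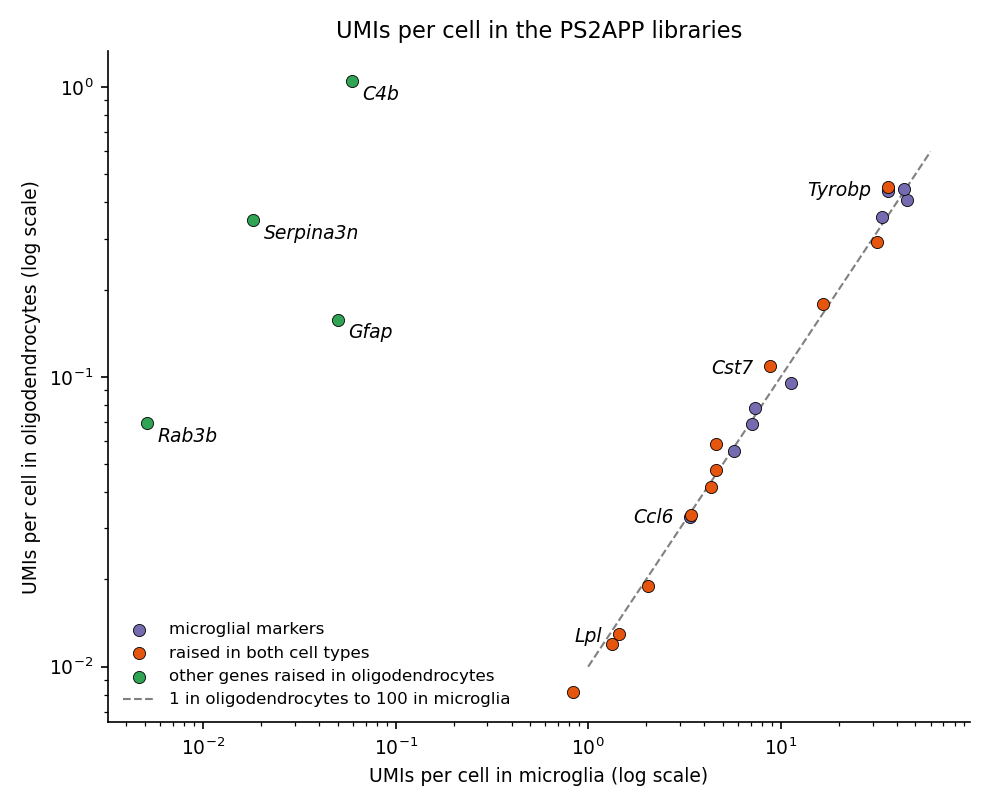
UMIs per cell in oligodendrocytes against UMIs per cell in microglia of the PS2APP libraries (log axes); points are genes, and the dashed line is a ratio of 1 to 100. Genes raised in both types lie along the line with the microglial markers, while C4b, Serpina3n, Gfap and Rab3b lie far above it. The plot makes no comparison with astrocytes.

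Gene groups in oligodendrocytes moved as follows. Disease-associated oligodendrocyte genes rose in 2 of 20, Serpina3n and C4b (7 adjusted over the list alone; adjusted p = 2.7e-19, and 0.00518 with an estimated correlation). Disease-associated microglia genes rose in 8 of 29 (16 adjusted over the list alone; adjusted p = 1.23e-44, and 0.00226 with an estimated correlation). Astrocyte homeostatic genes were lower as a list, with 0 of 19 past the threshold (6 adjusted over the list alone; adjusted p = 5.37e-16, and 0.00485 with an estimated correlation). Astrocyte markers beside them stood at 0 of 9 (3 adjusted over the list alone; adjusted p = 3.08e-13, and 0.0114 with an estimated correlation). Myelin genes did not pass (0 of 19; adjusted p = 0.0712). Of 22 pathway and state lists 13 passed, and 9 of them held with an estimated correlation.

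At 7 months alone, Cst7 rose in oligodendrocytes (adjusted p = 0.0334), from 0.460 to 28.8 ± 18.7 CPM, and no other gene passed. That count of 1 was 0 with the block (adjusted p for Cst7 = 0.201), and 0 by limma voom. It was also 0 without any single one of Non-Tg 7 months replicates 1, 2 and 3, PS2APP 7 months replicates 1 and 3, Non-Tg 15 months replicate 1, and PS2APP 15 months replicates 1 and 2, and adjusted p for Cst7 ran from 1.21e-44 to 0.632. At 15 months Serpina3n rose by 2.84 ± 0.25 (adjusted p = 0.000573) and C4b by 2.29 ± 0.38. Rab3b (ENSMUSG00000003411, chromosome 4, 108879063 to 108943324), a vesicle-trafficking GTPase gene, rose by 2.15 ± 0.26, from 5.80 to 25.6 CPM, and Plvap, a gene of endothelial fenestrae, by 2.67 ± 0.39, from 3.36 to 21.8 CPM. Vim, an intermediate filament gene, rose by 1.66 ± 0.21 and Anxa2, an annexin gene, by 1.92 ± 0.32; these 2 were chosen after their values were seen. Disease-associated oligodendrocyte genes rose in 4 of 20 at 15 months (11 adjusted over the list alone; adjusted p = 4.04e-23, and 0.00423 with an estimated correlation). MHC class I genes, which present antigen, stood at 0 of 9 (5 adjusted over the list alone; adjusted p = 1.61e-15, and 0.00995 with an estimated correlation).

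At 15 months 19 genes rose and 0 fell in oligodendrocytes by edgeR (42 with the block, 19 of them shared; 50 by DESeq2). The count was 2 without Non-Tg 15 months replicate 3, 5 without PS2APP 15 months replicate 1, 6 without Non-Tg 15 months replicate 1 or 2 or PS2APP 15 months replicate 2. It was 8 without Non-Tg 7 months replicate 3, 10 without PS2APP 7 months replicate 3 and 12 without PS2APP 15 months replicate 3. Serpina3n and Cst7 were kept on every omission, Rab3b was lost without Non-Tg 15 months replicate 3 (adjusted p = 0.0618, and from 3.91e-11 over its alternatives), and Plvap and C4b were lost on 5 and 8 of the 12. In the authors' sub-clusters, oligodendrocytes of Non-Tg 15 months replicate 1 lay mostly in number 4 (87.0%) and those of PS2APP 15 months replicate 1 in number 5 (83.7%). Replicates 2 of both groups lay in number 8 (76.7% of Non-Tg, 74.0% of PS2APP) and replicates 3 in number 9 (98.4% and 97.7%).

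Genotype by age asks whether the PS2APP difference changed between 7 and 15 months, and no single gene passed in any of the 3 types. By edgeR, C4b rose in oligodendrocytes at 15 months, yet the test of the difference between ages did not pass for it or for any other gene. The count was 0 in microglia (450 at unadjusted p under 0.05; DESeq2 0, limma voom 0), 0 in astrocytes (196; DESeq2 0, limma voom 0) and 0 in oligodendrocytes (176; DESeq2 1, limma voom 0). With the block the counts were 0, 1 and 0, and without a low-count filter 28, 2 and 16. As lists, MHC class I genes (adjusted p = 2.59e-11, and 0.0405 with an estimated correlation), disease-associated oligodendrocyte genes (2.59e-11 and 0.0386) and reactive astrocyte genes (2.9e-10 and 0.0386) differed between ages in oligodendrocytes by camera, with the larger rise at 15 months. By fry 0 of the 3 passed (adjusted p = 0.126, 0.126 and 0.0947), and with an estimated correlation the MHC class I call was lost on each of the 12 omissions and the other 2 on 10 each. The sex of the mice differs with age, so that age and sex cannot be separated in this difference.

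In Non-Tg mice, the comparison of 15 with 7 months returned few genes by edgeR, mainly sex-linked ones. Y-linked Ddx3y and Eif2s3y rose in all 3 cell types, Uty in astrocytes and oligodendrocytes, and Kdm5d in astrocytes. Beyond these, in astrocytes Thrsp, a lipogenesis gene, fell by 0.96 (adjusted p = 0.0353), the histone gene Hist2h3c2 fell by 1.97 (adjusted p = 0.00795) and Tsix fell by 7.21. In oligodendrocytes Cdh8, a cadherin gene, rose by 2.70, and in microglia the predicted gene Gm4017 rose; Tsix, Cdh8 and Gm4017 were chosen after their values were seen. The edgeR counts were 3 up and 0 down in microglia (1081 at unadjusted p under 0.05), 4 up and 3 down in astrocytes, and 4 up and 0 down in oligodendrocytes; the block could not be fitted here. By DESeq2 the counts were 12, 13 and 40 in the same order, and without a low-count filter 139, 55 and 155. In microglia the count was 7 without PS2APP 7 months replicate 3 and 11 without Non-Tg 15 months replicate 2. In astrocytes it was 14 without Non-Tg 7 months replicate 1 or PS2APP 7 months replicate 1, 4 without Non-Tg 7 months replicate 2, and 11 without PS2APP 7 months replicate 3. Leaving out Non-Tg 15 months replicate 2 gave 16, Non-Tg 15 months replicate 3 gave 3 and PS2APP 15 months replicate 3 gave 12. In oligodendrocytes it was 7 without PS2APP 15 months replicate 1. Thrsp was lost on 6 and Hist2h3c2 on 3 of the 12 omissions, with adjusted p up to 0.435. Xist, the RNA that silences the inactive X chromosome, lay at 1470 to 2265 CPM in 5 of the 6 libraries at 7 months and at 0.217 to 0.627 CPM in those at 15 months. PS2APP 7 months replicate 3 held 1 Xist UMI and 1.47 CPM of Y-linked genes. The fit shares its estimate of spread over all 4 groups, that library included. Xist did not pass in any of the 3 types, although over all cells Non-Tg libraries at 7 months held 1493 CPM or more. A gene can thus differ widely and not pass, so the short lists do not show that few genes differ with age or sex.

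**Figure D5:**
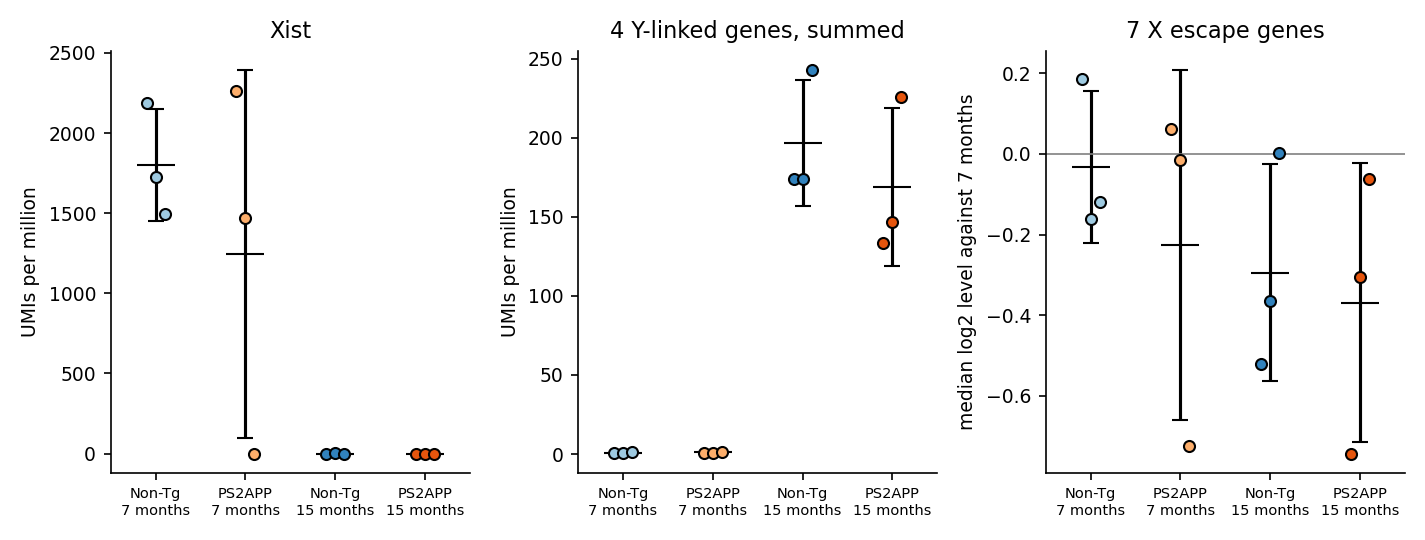
Xist and the sum of 4 Y-linked genes in CPM (linear axes), and the median log2 level of 7 genes that escape X inactivation, per library in the 4 groups; bars are the mean and SD of 3 libraries. In PS2APP 7 months replicate 3 Xist is at 0.0819 CPM and the escape genes are at -0.724.

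Among the other cell types, the potassium channel gene Kcnh7 (ENSMUSG00000059742, chromosome 2, 62693414 to 63184287) fell in Reelin cells by 2.44 ± 0.17 (adjusted p = 1.95e-07). It went from 257 ± 26.4 to 50.3 ± 11.3 CPM at 7 months and from 291 ± 76.8 to 49.7 ± 9.31 CPM at 15 months. It also fell in OPC by 2.20 ± 0.31 (adjusted p = 0.0135). Reelin cells had lower Aldoc (-1.80 ± 0.29) and Gpr37l1 (-1.82 ± 0.32), both abundant in astrocytes. Cst7 was at least 51.6-fold higher in Reelin cells and at least 17.5-fold in committed oligodendrocyte precursors (COP), and at least 75.3-fold at 7 months in OPC; COP also had Trem2 higher by 2.49 ± 0.40 (adjusted p = 0.0431). Summed over the PS2APP libraries, Cst7 stood at 50.1 CPM in Reelin cells, 36.2 in COP and 30.5 in OPC, against 1926 in microglia. Whether free RNA from microglia accounts for Cst7 in these types was not tested. Brain endothelial cells (BMEC) and pericytes had no gene past the threshold.

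By edgeR over both ages, OPC had 7 genes up and 1 down, Reelin cells 2 up and 4 down, excitatory neurons 6 up and COP 2 up, 22 in total and 77 with the block. BMEC had 0 of 4966 tested (108 at unadjusted p under 0.05; DESeq2 0, limma voom 0) and pericytes 0 of 4299 (97; DESeq2 0, limma voom 0). Aldoc and Gpr37l1 were lost on 8 and 10 of the 12 omissions, by limma voom and without the top 5% of cells by UMIs (adjusted p up to 0.238 and 0.32). Kcnh7 was lost in OPC without Non-Tg 7 months replicate 1, PS2APP 7 months replicate 2 or PS2APP 15 months replicate 2 (up to 0.0731). Both COP genes were lost by limma voom and without the top 5% of cells (up to 1 for Trem2 and 0.496 for Cst7). The OPC count was 4 without Non-Tg 7 months replicate 1, PS2APP 7 months replicate 2 or PS2APP 15 months replicate 2, and 5 without Non-Tg 7 months replicate 2 or PS2APP 15 months replicate 1. The Reelin cell count was 3 without Non-Tg 7 months replicate 1 or 3, PS2APP 7 months replicate 1 or 2, Non-Tg 15 months replicate 1 or 2, or PS2APP 15 months replicate 1 or 3. It was 11 without Non-Tg 7 months replicate 2 and 10 without Non-Tg 15 months replicate 3. The COP count was 0 without Non-Tg 7 months replicate 1 or 3, PS2APP 7 months replicate 1 or 3, Non-Tg 15 months replicate 1, or any PS2APP library at 15 months. It was 1 without Non-Tg 7 months replicate 2 or Non-Tg 15 months replicate 3, and 8 without PS2APP 7 months replicate 2. In pericytes 1 gene passed without PS2APP 15 months replicate 1. The total was 13 without Non-Tg 7 months replicate 1 or Non-Tg 15 months replicate 1 and 14 without PS2APP 15 months replicate 1.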

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

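The tests of Y-linked genes and of depth in the library without Xist, the fit without oligodendrocytes rich in microglial markers, the share test by age and the choice of the 3 patterns weighed here were made only after the results were seen.

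As lists, 27 groups of genes differed between 7 and 15 months in their PS2APP difference by camera with the preset correlation, 22 of them more positive and 5 more negative at 15 months. In microglia, MHC class I genes (adjusted p = 7.14e-05), interferon response genes (0.00326), MHC class II genes (0.0462) and mitochondrially encoded genes (3.61e-05) were more positive, and myelin genes (1.1e-08), oligodendrocyte markers (8.18e-05) and astrocyte homeostatic genes (0.00622) more negative. In astrocytes, reactive astrocyte genes (0.000174), complement genes (0.001), disease-associated oligodendrocyte genes (0.001), dissociation genes (2.55e-05), MHC class I genes (0.00233), interferon response genes (0.0035), homeostatic microglia genes (0.0267), mitochondrially encoded genes (0.0255) and microglial markers (6.93e-05) were more positive. In oligodendrocytes, disease-associated oligodendrocyte genes (2.59e-11), MHC class I genes (2.59e-11), reactive astrocyte genes (2.9e-10), interferon response genes (3.71e-07), homeostatic microglia genes (5.25e-06), microglial markers (8.08e-05), complement genes (2.99e-05), cholesterol synthesis genes (0.00194) and MHC class II genes (0.00197) were more positive, and astrocyte homeostatic genes (0.0102) and OPC genes (0.0102) more negative. With an estimated correlation 3 of the 27 held, all in oligodendrocytes: disease-associated oligodendrocyte genes (adjusted p = 0.0386), reactive astrocyte genes (0.0386) and MHC class I genes (0.0405). By fry 0 of the 27 passed (0.126, 0.0947 and 0.126 for those 3). The MHC class I call with an estimated correlation was lost on each of the 12 omissions (0.0526 to 0.169). The disease-associated oligodendrocyte call was kept without Non-Tg 15 months replicate 1 (0.0446) or PS2APP 15 months replicate 3 (0.0387), and the reactive astrocyte call without the same libraries (0.0446 and 0.0423). The 15 month mice also differ from the 7 month mice in sex, which was not tested separately.

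Other splits of the libraries into groups of the same sizes, 100 with the real one included, show how often a count over both ages is reached. In microglia 1 of the 100 splits gave as many genes (932, highest other 141), which argues against chance as the source of that count. As many genes came from 3 of 100 splits in astrocytes (6, highest other 29) and 3 in oligodendrocytes (19, highest other 47). The same held for 4 splits in OPC (8, highest other 539) and 2 in Reelin cells (6, highest other 6). Since other splits reached or passed the real count in each of these types, their low shares do not exclude chance. It cannot be excluded for COP with 13 of 100 (2; 205), or excitatory neurons with 9 (6; 298). Nor can it for the numbers of lists passed, with 11 of 100 splits in microglia (13 lists; highest other 16), 11 in astrocytes (9; 15) and 15 in oligodendrocytes (13; 16). A count of 0 is reached by every split, 100 of 100, and so cannot be tested in this way: BMEC (highest other 72), pericytes (6), and genotype by age in microglia (141), astrocytes (29) and oligodendrocytes (21). Splits that call several times the real count, as in astrocytes, OPC, COP and excitatory neurons, point to a structure of the samples. So do the counts of other splits in BMEC. For genotype by age, a split can regroup 1 age more than the other and so carry part of the genotype difference into that contrast. Its counts therefore do not tell whether the samples have a structure. Among the 9 other splits that, like the real one, part all 6 pairs of libraries with consecutive identifiers, the highest count over both ages was 0 in microglia, astrocytes, OPC and Reelin cells and 2 in oligodendrocytes; these 10 splits alone are too few for a share under 0.05. For genotype by age the highest among the same 9 was 15 in microglia, 4 in astrocytes and 0 in oligodendrocytes. For the reason given above, these counts do not tell whether parting the pairs removes a structure. In COP and excitatory neurons the real split parts 5 pairs, and the highest count among the 14 other splits that do so was 1 in each; 15 splits are also too few. With these pairs as a block the counts over both ages were 1609 in microglia, 17 in astrocytes and 25 in oligodendrocytes.

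For the comparisons of 3 with 3 libraries the 10 splits are too few for a share under 0.05. In microglia the counts were 252 at 7 months, 381 at 15 months and 3 for age in Non-Tg, with a highest other of 0 each. In astrocytes they were 2 (highest other 0), 6 (2) and 7 (1), and in oligodendrocytes 1 (0), 19 (40) and 4 (0). The split with 40 genes at 15 months points to a structure of the samples, and with the block 42 genes passed there. Counting the real split, 1 of 10 splits reached the real count in each case except oligodendrocytes at 15 months, with 2.

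Transcripts abundant in microglia were higher in oligodendrocytes of PS2APP mice, as with Cst7 at 0.109 UMIs per oligodendrocyte and 8.82 per microglial cell. Doublets of an oligodendrocyte and a microglial cell are argued against, since 1.4% ± 1.4 (SD, 6 PS2APP libraries) of the UMIs of the 12 genes lay in oligodendrocytes with 10 or more UMIs of microglial markers. Without these cells 13 of the 19 genes passed and 0 others; the 6 lost had adjusted p of 0.0526 to 0.0699, and the largest move in their log2 fold change was from 1.96 to 1.88. Free RNA from microglia is a candidate explanation: the median log2 ratio between oligodendrocytes and OPC was -0.29 for these genes and -0.23 for microglial markers, a difference of -0.06 ± 0.15 (SD). Expression of a part of these genes by oligodendrocytes at a level far under that of microglia stays open.

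Serpina3n and C4b were higher in oligodendrocytes of PS2APP than of Non-Tg mice. In PS2APP they stood at 0.347 and 1.05 UMIs per oligodendrocyte and 0.133 and 0.666 per astrocyte. UMIs per cell are not scaled to depth: C4b summed over the PS2APP libraries stood at 257 CPM in oligodendrocytes and 274 in astrocytes. Free RNA from astrocytes is argued against, since the lower of the genes' ratios of oligodendrocytes to astrocytes lay at least 12.6 times above that of the highest astrocyte marker in each of the 6 PS2APP libraries, and for microglia the same value was 522. No single library sets the rise at 15 months: the lowest log2 fold change on any omission was 2.13, for C4b without Non-Tg 15 months replicate 3. A response of oligodendrocytes in PS2APP mice stays open as a hypothesis, found and tested on the same data, as does the assignment of reads shared with paralogs, which was not tested.

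Nearly no Xist was found in PS2APP 7 months replicate 3, with 1 UMI where the lowest other 7 month level would give 17942, which argues against low depth. A male mouse or a swap with a 15 month library is argued against by its Y-linked genes, at 1.47 CPM against 133.5 CPM or more in the 15 month libraries. A pair of active X chromosomes is argued against by 122 X-linked genes, whose median log2 level was -0.01 relative to the other 7 month libraries. A single X chromosome may account for it, since genes that escape X inactivation had a median of -0.724, with 7 of 7 below 0. The 15 month libraries spread from -0.743 to 0.003 on that measure, so this value alone is loose evidence.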

How the results depend on the processing

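No test in this part was chosen after the results were seen, except the fit without oligodendrocytes or astrocytes that hold 10 or more UMIs of microglial markers, which gave 13 genes in oligodendrocytes and 6 in astrocytes over both ages. The 6 oligodendrocyte genes it lost moved from 1.96 to 1.88 log2 at most, with adjusted p of 0.0526 to 0.0699. Of the gene calls examined, all 140 kept their direction and side of the threshold with DESeq2 size factors, with the DESeq2 test and with no low-count filter. So did 9 of 9 microglial shares with no thinning or thinning to 500 UMIs. With the block 133 gene calls were kept and 5 were weaker, with limma voom 123 and 17, and without the top 5% of cells by UMIs 123 and 16. Over all omissions of 1 library 1508 results were kept and 273 were weaker, a tally that also holds the 9 microglial shares. The gene calls examined were picked by size of change, small p or mention in the text, and do not stand for all calls. The difference of Mapt in excitatory neurons, not past the threshold, was -0.07 and ran from -0.195 to 0.04 over the omissions of 1 library, turning to 0.04 without PS2APP 15 months replicate 1. No cell type share passed under any alternative, though by permutation no single type could pass alone. Leaving out cells under 1000 UMIs removed 0 cells and so tested nothing. The cause was not tested for any change below, except that with no filter more genes are tested and an omission leaves fewer libraries.

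With the block, over both ages, the counts were 1609 in microglia, 17 in astrocytes, 22 in COP, 17 in OPC, 21 in Reelin cells and 17 in excitatory neurons, with 77 for all other types together. They were 536, 3 and 0 in microglia, astrocytes and oligodendrocytes at 7 months, 927, 12 and 42 at 15 months, and 1 in astrocytes for genotype by age. The DESeq2 test gave 13 in astrocytes, 44 in oligodendrocytes, 4 in COP, 13 in OPC, 13 in Reelin cells, 10 in excitatory neurons and 40 for the other types over both ages. It gave 4 in oligodendrocytes at 7 months, 665, 10 and 50 in the 3 main types at 15 months, 1 in oligodendrocytes for genotype by age, and 12, 13 and 40 for age in Non-Tg. Limma voom gave 8 in oligodendrocytes, 0 in COP, 5 in OPC, 3 in Reelin cells and 12 for the other types over both ages, 0 in oligodendrocytes at 7 months and 5 in microglia for age in Non-Tg. Without the top 5% of cells by UMIs the counts were 12 in oligodendrocytes, 0 in COP, 3 in Reelin cells and 3 in excitatory neurons. With no filter they were 23 in astrocytes, 89 in oligodendrocytes, 1 in BMEC, 29 in COP, 30 in OPC, 24 in Reelin cells, 24 in excitatory neurons, 3 in pericytes and 111 for the other types over both ages. For the 3 main types with no filter they were 390, 7 and 27 at 7 months, 1033, 31 and 85 at 15 months, 28, 2 and 16 for genotype by age, and 139, 55 and 155 for age in Non-Tg. With an estimated correlation 2 lists passed in microglia, and by fry 6 in oligodendrocytes.

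Leaving out 1 library at a time gave 605 to 1310 genes in microglia over both ages, 117 to 259 at 7 months, 158 to 1006 at 15 months, 0 for genotype by age and 3 to 11 for age in Non-Tg. Astrocytes gave 6 to 10, 0 to 4, 1 to 9, 0 and 3 to 16, and oligodendrocytes 4 to 16, 0 to 1, 2 to 23, 0 and 3 to 7 in the same order. BMEC gave 0, COP 0 to 8, OPC 4 to 9, Reelin cells 3 to 11, excitatory neurons 4 to 8, pericytes 0 to 1 and all other types together 13 to 23. The total could not be formed for 3 of the libraries, which held under 20 cells of at least 1 of the types. With 3 libraries per group, a fold of 1.5 was recovered in 18.4% of simulated genes or fewer, so that smaller changes can be missed at this depth.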

Other observations

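The tests for marker lists of other cell types beside these groups were planned; the share test by age and the genes named outside the rule were chosen only after the results were seen. In microglia 5 further gene groups passed over both ages by camera with the preset correlation, and 0 of these 5 with an estimated one. Of 16 cytokine and chemokine genes 6 rose (7 adjusted over the list alone; adjusted p = 7.48e-05, and adjusted p = 0.126 with an estimated correlation). Csf1, a growth factor for myeloid cells, rose by 2.69 ± 0.21, the neutrophil chemokine gene Cxcl2 by 2.18 ± 0.29 and interleukin 1 beta (Il1b) by 2.06 ± 0.36. Cholesterol synthesis genes rose in 2 of 17 (7 adjusted over the list alone; adjusted p = 3.11e-05, and adjusted p = 0.133 with an estimated correlation). Among them the demethylase gene Cyp51 rose by 0.93 ± 0.22, a call lost without Non-Tg 7 months replicate 2 or 3 (adjusted p up to 0.062). MHC class I genes rose in 4 of 11 (7 adjusted over the list alone; adjusted p = 3.96e-05, and adjusted p = 0.14 with an estimated correlation), with B2m, the light chain of class I molecules, at 0.84 ± 0.14. MHC class II genes stood at 0 of 6 (3 adjusted over the list alone; adjusted p = 0.00143, and adjusted p = 0.238 with an estimated correlation). Astrocyte homeostatic genes fell in 3 of 14 in microglia (6 adjusted over the list alone; adjusted p = 0.000134, and adjusted p = 0.133 with an estimated correlation).

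In astrocytes, MHC class I genes stood at 0 of 6 over both ages (2 adjusted over the list alone; adjusted p = 4.86e-07, and 0.0355 with an estimated correlation). Lysosome genes stood at 0 of 17 (2; 1.22e-07, and 0.0143 with an estimated correlation) and complement genes at 0 of 4 (4; 4.26e-06, and adjusted p = 0.0649 with an estimated correlation). In oligodendrocytes, cytokine and chemokine genes rose in 3 of 12, namely Ccl3, Ccl4 and Cxcl2 (5 adjusted over the list alone; adjusted p = 8.42e-17, and 0.0218 with an estimated correlation). MHC class II genes stood at 0 of 6 there (1; 8.58e-10, and 0.0388 with an estimated correlation). Transgene-related genes were higher as a list in oligodendrocytes with 0 of 5 past the threshold (2 adjusted over the list alone; adjusted p = 6.72e-06, and 0.00804 with an estimated correlation), Thy1 at 2.13 (adjusted p = 0.215) and Psen2 at 0.55 (adjusted p = 0.34). Gfap lay at 0.158 UMIs per oligodendrocyte and 2.95 per astrocyte of PS2APP mice, a ratio of 0.0535, against 0.0148 for Aldoc and 0.0103 for Slc1a2. Only these 2 transcripts are set beside it, and free RNA from astrocytes was not tested for Gfap.

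The difference between ages in the PS2APP effect on cell shares had its lowest exact permutation p of 0.015 for COP, with an adjusted p of 0.213 over the 16 types. By edgeR on cell counts, astrocytes differed by -0.94 log2 and T cells by 1.28, with an adjusted p of 0.0542 each. Mitochondrially encoded transcripts took 1.12% to 1.99% of UMIs per library.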
